A study of Rattus norvegicus with 6 samples.

How the data were processed

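RNA was measured by sequencing in hippocampus of 6 Sprague Dawley rat samples, 3 labelled single prolonged stress (SPS) and 3 labelled Control. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into libraries with a stranded total RNA kit and sequenced for 150 cycles. Per the submitters' processing notes, CASAVA 1.8 and HISAT2 were used. The same notes name the human build hg19, although the gene identifiers are Ensembl rat identifiers. The rat build, the annotation release, the quantifier and the use of strand in counting are not given in the sources used here. Coordinates are therefore printed as the deposited table gives them, without a build, and antisense or overlapping genes could not be separated beyond what the table does.

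The deposited table held 22062 genes, all of them protein coding, with 1 FPKM value and 1 estimated count per gene and library, per the file headers. The FPKM values, fragments scaled to transcript length and library size, were made by the authors and their totals differed between libraries. The estimated count columns deposited by the authors were not whole numbers. In each library 99.5% to 99.6% of the values above 0 were whole multiples of a single step, to within 0.05 reads, and the step ranged from 0.614 in Control replicate 1 to 1.79 in SPS replicate 2. The values were divided by the step of their library and rounded to whole reads, since the scaling had made the deposited totals nearly equal and hidden the depth. The recovered depth was 11838770, 5321132 and 4786503 reads in Control replicates 1 to 3 and 11148531, 4081184 and 5768628 in SPS replicates 1 to 3. Between 11670 and 13235 genes had at least 10 reads in a library. The length column of the table gave the span of the locus, so effective transcript length was taken from the ratio of count to FPKM.

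The test planned for count columns was the main test: edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the tool's own expression filter, a quasi-likelihood fit on group alone and 2-sided p-values with Benjamini-Hochberg adjustment over the 12441 genes that passed the filter. The table held both units, and the plan named limma 3.58.1 on log2(FPKM + 1) for FPKM, with genes of mean FPKM of at least 0.5. The count test was chosen from the units before any result was seen, and limma was run beside it. CPM values are TMM-normalised read counts scaled to a common library size (counts per 1e+06 reads), and log2 fold changes are SPS minus Control. The standard error (SE) of a log2 fold change in edgeR was its absolute value divided by the square root of the test's F statistic. A fold change of a gene at 0 in some libraries depends on the tool's prior count.

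Gene lists of 40 cell types and functions, and the rule for named genes, were fixed before the data were examined. The lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 40 lists, and again with an estimated correlation and with fry. Named genes were the 10 higher and 10 lower genes with the smallest p and a mean CPM of at least 1, leaving out provisional symbols; the 4 members with the smallest p in each passing list; and 18 genes of the stress response, plasticity, glia and blood. Other genes are marked as chosen after their values were seen.

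The labels number the samples 1 to 3 in each group without saying what a number shares. Deviations from the group means correlated across genes between samples of the same number, at 0.41, 0.37 and 0.67 for replicates 1, 2 and 3, and at no more than 0.16 between samples of different number. All 3 correlations were over the limit of 0.1 set beforehand, so the numbers were taken to pair the samples from the data, and a fit with replicate as a block was run beside the unpaired fit. The 3 deviations of a group cancel out in each gene, so the 3 correlations are not independent. Likeness of numbers 1 and 3 alone can raise the value of number 2 and lower those of different numbers. Without centring, log CPM of Control replicate 2 correlated at 0.772 with SPS replicate 2 and at 0.888 with Control replicate 1. The pairing of number 2 is therefore less certain than that of numbers 1 and 3. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom lay between 7.01 and 156.

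The fits were tested on simulated counts with known changes. In the unpaired design, run on 12069 simulated genes, 0% of genes changed 2-fold were recovered, 6% of those changed 4-fold, 44.9% of those changed 8-fold and 69.6% of those changed 16-fold. In the design with the replicate block, run on 12129 simulated genes, the shares were 14%, 68%, 87.5% and 93.9%. There were 1 and 9 false calls. The unpaired simulation left out the likeness of libraries with the same number, so its shares and false calls may differ from those in the real libraries.

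The alternatives comprised the replicate block, DESeq2 1.42.0, other filters, scalings and pseudocounts, and leaving out each library in turn. The other pseudocounts and scalings were planned for FPKM values and were run with limma. Its fit on log2(FPKM + 1), planned as the main test for FPKM alone, became an alternative after the table was seen to hold both units. Added after seeing the data were that fit with the replicate block, summing rows that share a symbol, the counts as deposited, RLE, upper-quartile and no normalisation factors, a transcript length correction with the block, library quality weights with the block, and leaving out both libraries numbered 2. Symbols shared by several rows numbered 233, and identifiers rather than symbols were tested. No fold change or p-value made by the authors was used. All per-sample columns of the table were used.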

Results

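The hippocampus of rats exposed to single prolonged stress (SPS), a rodent procedure used as a model of post-traumatic stress, was compared with that of rats kept in their home cages. The stressed rats were restrained for 2 hours, swam for 20 minutes in water at 24 °C, rested for 15 minutes and were then anaesthetised until unconscious. RNA was sequenced from 3 SPS and 3 Control samples. The labels do not say how long after stress the tissue was taken, nor expressly that each sample is a separate animal, so p-values measure only the spread between these samples. Depth ranged from 4081184 reads in SPS replicate 2 to 11838770 in Control replicate 1, and 12441 genes were tested.

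The question was which hippocampal transcripts differ after SPS. Transcripts of oligodendrocytes, the myelinating glia, and of ependymal cells, the ciliated lining of the ventricles, lay higher in SPS as groups. Mitochondrially encoded transcripts and immediate-early genes, which respond quickly to neuronal activity, lay lower as groups. These 4 calls came from camera at a preset correlation between genes, and none held with an estimated correlation (adjusted p = 0.551 for both the oligodendrocyte and the ependymal list, 0.999 for the mitochondrial and 0.950 for the immediate-early list). The mitochondrial and immediate-early calls were also lost without SPS replicate 3 (adjusted p = 0.778 and 0.294), among other libraries. Transcripts of the choroid plexus, the epithelium that secretes cerebrospinal fluid, were very high in SPS replicate 2 and not in the other SPS samples. No single gene passed the test over all genes.

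By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 12441 genes differed between the groups, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 42 genes, against 622 expected by chance, and 37 of them differed by at least 2-fold, 34 higher and 3 lower in SPS. Of the 34 higher genes, 31 had their highest level in SPS replicate 2. DESeq2 also gave 0 genes by adjusted p and 84 at an unadjusted p under 0.05. The fit by limma on log2(FPKM + 1) gave 0 and 65, with 30 higher and 31 lower among the 61 that differed at least 2-fold. With the replicate block edgeR gave 0 genes, with 172 at an unadjusted p under 0.05. The 37 genes became 18 without SPS replicate 2, 11 without Control replicate 2, 217 without Control replicate 3, 152 without SPS replicate 1 and 110 without SPS replicate 3. Genes whose groups did not overlap made up 2.94% of those tested, 192 higher and 174 lower in SPS, where chance gives 10%. The 622 genes and the 10% assume 6 exchangeable libraries and leave out the likeness of libraries with the same number, which makes the groups overlap more. The biological coefficient of variation, from the single dispersion fitted to all genes in common, was 61.1%, and 39.6% with the replicate block.

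Oligodendrocyte markers formed the list with the smallest p. Of 21 measured genes, 20 had a positive fold change and 18 were higher in SPS in all 3 same-numbered pairs, with a median log2 fold change of 0.88. The pair medians were 0.28, 1.47 and 0.35 for replicates 1, 2 and 3. Mal, a myelin membrane protein, was at 266 ± 22.5 CPM in Control and 490 ± 193 in SPS (mean ± SD, n = 3), Mobp, a myelin structural protein, at 347 ± 72.6 and 713 ± 343, and Tf, the iron carrier transferrin made by oligodendrocytes and choroid plexus in brain, at 458 ± 102 and 1325 ± 1187. All 3 were highest in SPS replicate 2, where Tf was at 2694 CPM and choroid plexus transcripts were also highest. Without that library the log2 fold changes went from 0.88 to 0.51 for Mal, from 1.04 to 0.60 for Mobp and from 1.53 to 0.48 for Tf. Mbp, myelin basic protein, an abundant member chosen after its values were seen, was at 5665 ± 1827 and 10997 ± 6874 CPM, with 18751 in SPS replicate 2. The list ranked above the other genes in camera (adjusted p = 6.11e-20 over 40 lists), but not with an estimated correlation between its genes (adjusted p = 0.551). Without SPS replicate 2 the median was 0.48 and without both libraries numbered 2 it was 0.31. The list passed at the preset correlation in both (adjusted p = 5.79e-07 and 1.27e-06) and in all 25 alternatives, with adjusted p from 2.37e-21 to 1.27e-06. No member passed the edgeR test, either over all genes or adjusted over the list alone.

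Precursor markers of the oligodendrocyte lineage had a median of 0.58 over 11 genes, 9 of them positive and 6 higher in all 3 pairs (camera adjusted p = 0.000263, and adjusted p = 0.628 with an estimated correlation). The pair medians were 0.24, 1.30 and 0.26. Without both libraries numbered 2 the median was 0.19 and the list did not pass (adjusted p = 0.0814). Sox10, a transcription factor of the lineage, was at 73.9 ± 5.63 CPM in Control and 144 ± 76.5 in SPS, and Gpr17, a receptor of differentiating precursors, at 19.9 ± 12.8 and 40.1 ± 22.6. Without SPS replicate 2 the log2 fold changes went from 0.97 to 0.45 for Sox10 and from 1.02 to 0.57 for Gpr17. The median was 0.34 without SPS replicate 3 (adjusted p = 0.0312) and 0.36 without Control replicate 2 (adjusted p = 0.0122). At the preset correlation the adjusted p ranged from 1.76e-05 to 0.0814 over the alternatives. Sox10 lies on a span shared by 10 genes in the table and Gpr17 on one shared by 3, so their reads may include those of neighbours. Erbb3, a neuregulin receptor of the same lineage (ENSRNOG00000004964, chromosome 7, 2989339 to 3010350) that belonged to no fixed list, had the second smallest p among the named higher genes. It was at 36.9, 30.2 and 48.0 CPM in Control replicates 1 to 3 and at 62.3, 82.2 and 81.0 in SPS replicates 1 to 3, a log2 fold change of 0.97 ± 0.33 (SE, unadjusted p = 0.0210 and adjusted p = 1.00 in edgeR).

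**Figure D1:**
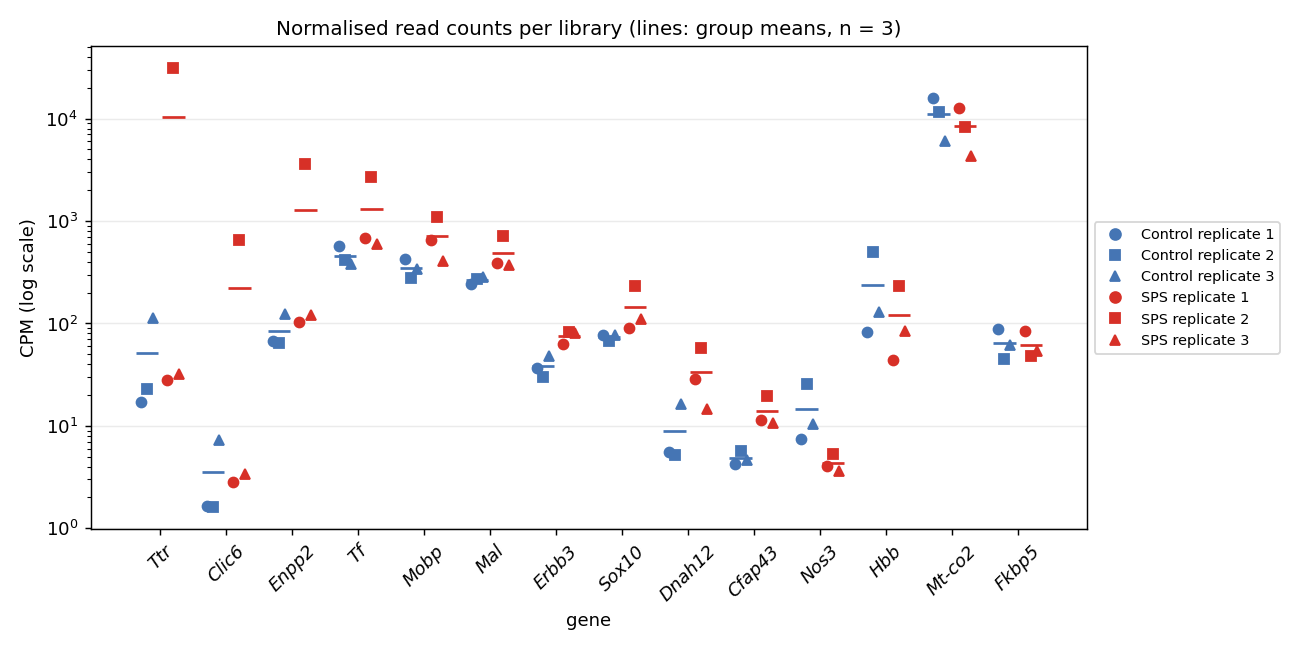
Normalised read counts (CPM, log scale) of 14 genes in each of the 6 libraries, with blue for Control, red for SPS, a marker shape per replicate number and short lines at the group means (n = 3). Ttr reached 31254 CPM in SPS replicate 2 and at most 113 in the other 5 libraries, while Erbb3 and Cfap43 were higher in each SPS library than in each Control library.

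Ependymal markers had a median log2 fold change of 1.89 over 12 genes, 11 of them positive and 7 higher in all 3 pairs (camera adjusted p = 7.08e-17, and adjusted p = 0.551 with an estimated correlation). The pair medians were 1.05, 3.36 and 0.79. Cfap43, a protein of motile cilia (ENSRNOG00000036585, chromosome 1, 267511522 to 267598639), was at 4.86 ± 0.73 CPM in Control and 13.9 ± 5.04 in SPS (SD, n = 3), with every SPS library above every Control library. Dnah12, an axonemal dynein, was at 9.01 ± 6.30 and 33.6 ± 22.1. Cfap126, another cilium protein, was at 1.93, 0 and 1.54 CPM in Control replicates 1 to 3 and 3.81, 26.4 and 5.93 in SPS replicates 1 to 3. Cfap99, a cilium and flagellum protein named by its p alone, was at 1.69 ± 0.23 and 10.5 ± 10.4. Without SPS replicate 2 the log2 fold changes went from 1.91 to 1.27 for Dnah12, from 3.33 to 2.02 for Cfap126 and from 2.61 to 1.40 for Cfap99. Without SPS replicate 2 the median was 1.09 and the list passed camera at the preset correlation (adjusted p = 6.44e-06). At that correlation the adjusted p lay between 2.37e-17 and 1.13e-05 over all 25 alternatives. The list did not pass with fry (adjusted p = 0.983).

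Choroid plexus markers had a median log2 fold change of 3.28 over the 13 genes of 25 that were tested, all positive (camera adjusted p = 1.03e-10, and adjusted p = 0.786 with an estimated correlation). The level came from SPS replicate 2, where Ttr, the thyroxine carrier transthyretin (ENSRNOG00000016275, chromosome 18, 15532962 to 15540177), reached 31254 CPM and took 3.31% of all reads. Ttr was at 17.2, 22.9 and 113 CPM in Control replicates 1 to 3 and at 28.2 and 31.8 in SPS replicates 1 and 3. Clic6, an intracellular chloride channel, was at 659 CPM in that library and at most 7.26 in the others. Enpp2, the lysophospholipase D autotaxin, which the oligodendrocyte list also holds, was at 3634 against at most 124, and Kcne2, a potassium channel subunit, at 171 against at most 4.55. Without SPS replicate 2 the median was −0.21 and the list did not pass (adjusted p = 0.547). At the preset correlation this was the highest over the alternatives, where the lowest was 1.95e-19. Oligodendrocyte and ependymal markers were also highest in this library, at 1.02 and 2.02 above the mean of the 6 libraries on the log2 scale.

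**Figure D2:**
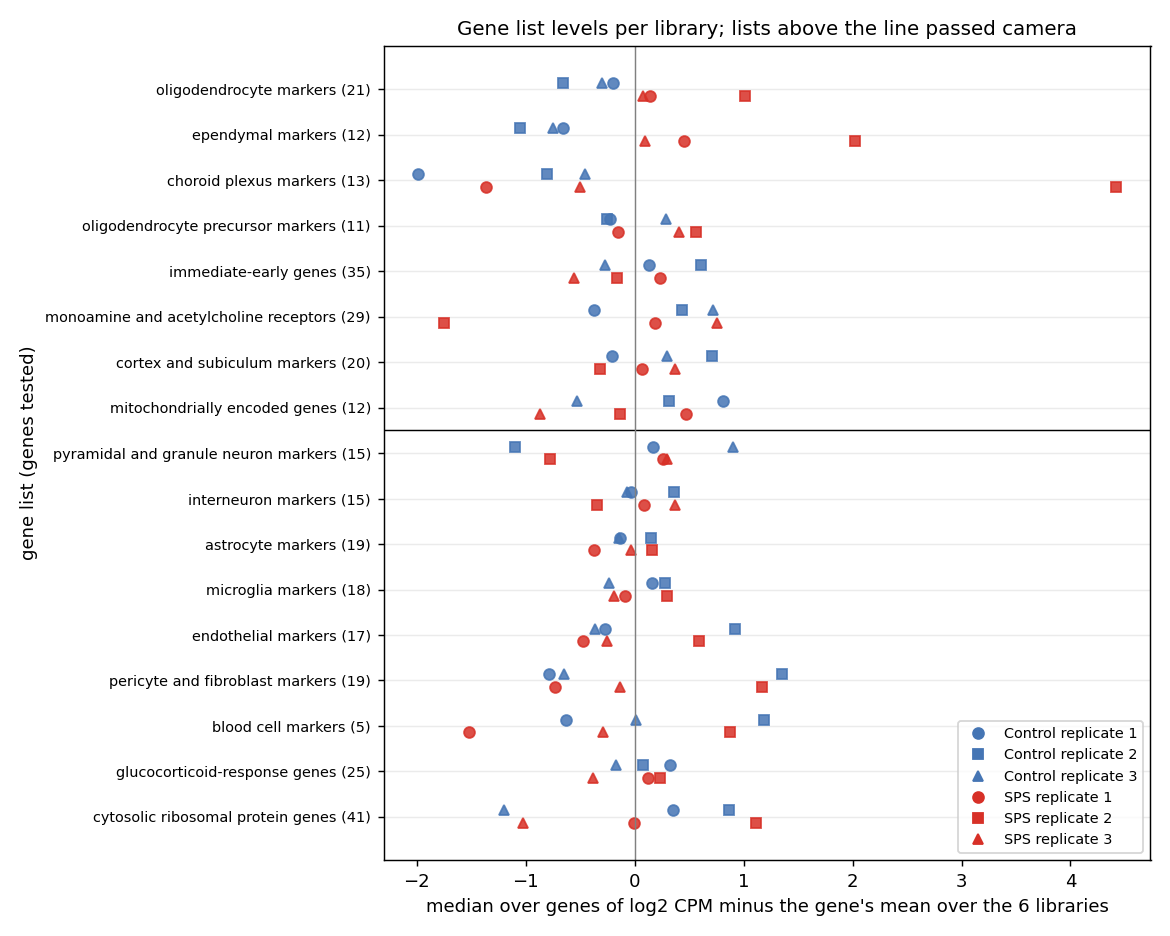
Median over the genes of each list of log2 CPM minus the gene's mean over the 6 libraries, 1 point per library, with blue for Control, red for SPS and a marker shape per replicate number; the number of genes tested stands in parentheses, and lists above the line passed camera at the preset correlation. Choroid plexus markers stood at 4.41 in SPS replicate 2, and oligodendrocyte markers lay between −0.66 and −0.20 in Control and between 0.08 and 1.02 in SPS.

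Mitochondrially encoded genes, which code for subunits of the respiratory chain, had a median log2 fold change of −0.34 over 12 genes, with 0 positive and 8 lower in all 3 pairs. Pair by pair, the medians were −0.26, −0.35 and −0.45 for replicates 1, 2 and 3. Mt-co2, a cytochrome c oxidase subunit, was at 11200 ± 4992 CPM in Control and 8458 ± 4160 in SPS (SD, n = 3), and Mt-atp8, an ATP synthase subunit whose span overlaps other genes, at 1852 ± 477 and 1340 ± 576. The list passed camera narrowly (adjusted p = 0.0490, and adjusted p = 0.999 with an estimated correlation) and did not pass without Control replicate 1 (median −0.03, adjusted p = 0.813), SPS replicate 2 (median −0.28, adjusted p = 0.0923) or SPS replicate 3 (median −0.10, adjusted p = 0.778). Those fits had no replicate block and left the library of the same number unmatched. With the block and all libraries the list passed camera (adjusted p = 1.76e-05), but not with an estimated correlation (adjusted p = 0.974). At the preset correlation the adjusted p of the list ranged from 3.05e-07 to 0.813 over the alternatives. The mitochondrial share of reads was 15.6%, 11.2% and 5.94% in Control replicates 1 to 3 and 13.2%, 8.95% and 5.25% in SPS replicates 1 to 3. This share differed more between replicate numbers than between groups, and it was lower in SPS in all 3 pairs. Nuclear-encoded oxidative phosphorylation genes did not pass (40 genes, median −0.11, adjusted p = 0.767). They passed with a negative median without Control replicate 3 (−0.47, adjusted p = 2.77e-05) and without SPS replicate 2 (−0.54, adjusted p = 7.69e-07), and with a positive median without Control replicate 2 (0.13, adjusted p = 0.0379) and without SPS replicate 3 (0.18, adjusted p = 0.0249).

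Immediate-early genes had a median log2 fold change of −0.25 over 35 genes, 8 of them positive, with 6 higher and 8 lower in all 3 pairs (camera adjusted p = 0.000798, and adjusted p = 0.950 with an estimated correlation). The pair medians were 0.13, −0.82 and −0.44 for replicates 1, 2 and 3. Egr4, an activity-induced transcription factor, was at 30.7 ± 27.3 CPM in Control and 11.3 ± 8.13 in SPS, Klf2, a Kruppel-like factor also expressed in endothelium, at 12.1 ± 9.45 and 3.25 ± 2.36, and Nr4a2, a nuclear receptor, at 109.9 ± 42.2 and 52.6 ± 36.7. Control replicate 2 held the highest level of each, 61.9 CPM for Egr4 and 22.7 for Klf2. It also held the highest endothelial markers, at 0.92, and pericyte and fibroblast markers, at 1.35 above the mean of the 6 libraries. Without it the log2 fold changes went from −1.44 to −0.42 for Egr4 and from −1.88 to −1.06 for Klf2. That of Nr4a2 went from −1.06 to −0.57 without SPS replicate 2. Fos was at 13.9 ± 10.8 and 10.4 ± 6.63. Arc was at 205 ± 40.5 and 151 ± 68.4, and Egr1 at 200 ± 41.3 and 139.5 ± 35.2 (SD, n = 3). The list did not pass without Control replicate 2 (median −0.08, adjusted p = 0.214) or without SPS replicate 3 (median −0.26, adjusted p = 0.294). At the preset correlation its adjusted p ranged from 0.000104 to 0.294 over the alternatives.

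Monoamine and acetylcholine receptors had a median of −0.25 over 29 genes (camera adjusted p = 0.0278, and adjusted p = 0.999 with an estimated correlation), and cortex and subiculum markers a median of −0.40 over 20 genes (adjusted p = 0.0278, and 0.786 as the adjusted p with an estimated correlation). Both lost the call with the replicate block (adjusted p = 0.114 for each), where the medians were −0.28 and −0.48. The large decrease was in the pair numbered 2. For replicates 1, 2 and 3 the pair medians were 0.34, −1.82 and 0.08 for the receptors. For cortex and subiculum markers they were 0.12, −1.37 and −0.14. Htr5b, a serotonin receptor, was at 32.5, 36.4 and 28.4 CPM in Control replicates 1 to 3 and 25.4, 7.87 and 17.1 in SPS replicates 1 to 3, while Htr2c, a serotonin receptor also abundant in choroid plexus, was at 55.0 ± 35.4 and 197 ± 205 (SD, n = 3) and highest in SPS replicate 2, at 427. Cux2, a marker of upper cortical layers, was at 49.4 ± 48.4 and 23.9 ± 5.01, and Calb1, a calcium-binding protein of granule and other neurons, at 83.8 ± 38.7 and 54.3 ± 30.1. Cux2 was at 104.5 CPM in Control replicate 2. Without that library its log2 fold change went from −1.05 to 0.12 and that of Calb1 from −0.62 to −0.21. Without SPS replicate 2 it was −0.22 for Calb1, and went from 1.84 to 0.57 for Htr2c and from −0.94 to −0.61 for Htr5b. The receptor list did not pass without SPS replicate 2 (median 0.05, adjusted p = 0.427), without Control replicate 3 (median 0.04, adjusted p = 0.666) or without SPS replicate 1 (median −0.23, adjusted p = 0.125). The cortex and subiculum list did not pass without Control replicate 2 (median −0.23, adjusted p = 0.220), Control replicate 3 (median −0.42, adjusted p = 0.197), SPS replicate 1 (median −0.45, adjusted p = 0.164) or SPS replicate 2 (median −0.15, adjusted p = 0.357). Over the alternatives at the preset correlation the adjusted p ranged from 4.17e-05 to 0.832 for the receptors and from 0.00385 to 0.995 for the cortex and subiculum list.

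The other 32 lists did not pass, with adjusted p between 0.298 and 0.999, although 14 of them passed in at least 1 alternative. Glucocorticoid-response genes had a median of −0.07 over 25 genes (adjusted p = 0.871). Fkbp5, a co-chaperone of the glucocorticoid receptor, was at 64.9 ± 21.2 CPM in Control and 61.9 ± 19.3 in SPS, Sgk1, a glucocorticoid-induced kinase, at 117 ± 30.9 and 127 ± 53.2, and Tsc22d3, also induced by glucocorticoids, at 63.5 ± 9.23 and 57.4 ± 16.9 (SD, n = 3). The log2 fold change of Nr3c1, the glucocorticoid receptor, was 0.23 ± 0.61, and that of Nr3c2, the mineralocorticoid receptor, 0.22 ± 0.87 (SE). Bdnf, a neurotrophin, was at 49.5 ± 3.03 and 40.4 ± 16.8 CPM, its receptor Ntrk2 at 863 ± 526 and 861 ± 550, and the cannabinoid receptor Cnr1 at 321 ± 234 and 369 ± 309. Crhr1 and Crh, the receptor and the peptide of corticotropin release, had 45 and 55 reads over the 6 libraries and the cytokine Il1b 1 read, so they were not tested.

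Among the other functional lists, synaptic vesicle genes had the smallest p (29 genes, median −0.12, adjusted p = 0.298) and passed without Control replicate 2 (median −0.27, adjusted p = 0.0113) and without SPS replicate 3 (median −0.47, adjusted p = 0.00144). They were followed by receptors and hormones of the stress axis (16 genes, median −0.18, adjusted p = 0.373) and circadian clock genes (22 genes, median −0.16, adjusted p = 0.445). Unfolded-protein-response genes had a median of 0.11 (adjusted p = 0.636), cholesterol synthesis genes 0.09 (adjusted p = 0.675), interferon-response genes −0.02 (adjusted p = 0.871) and neurotrophin and plasticity kinases −0.03 (adjusted p = 0.999). The median, the mean and the test differed in sign for 10 lists, none of which passed: heat-shock genes, complement and antigen presentation, pyramidal and granule neuron markers, cytokines, interneuron markers, apoptosis genes, GABA receptors and synthesis, cytosolic ribosomal protein genes, pericyte and fibroblast markers, and endocannabinoid genes.

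Among markers of other cell types, astrocytes had a median of −0.03 over 19 genes (adjusted p = 0.871), microglia −0.06 over 18 (adjusted p = 0.603), endothelial cells −0.18 over 17 (adjusted p = 0.905) and pyramidal and granule neurons 0.02 over 15 (adjusted p = 0.871). Microglial markers passed without SPS replicate 2 (median −0.29, adjusted p = 0.0285) and neuronal markers without Control replicate 2 (median −0.32, adjusted p = 0.0105). Endothelial markers passed with a positive median without Control replicate 2 (0.43, adjusted p = 0.0105) and a negative one without SPS replicate 2 (−0.55, adjusted p = 0.000686). Gfap, an astrocyte filament protein, was at 846 ± 220 CPM in Control and 960 ± 170 in SPS, and Aif1, a microglial protein, at 18.1 ± 9.46 and 19.1 ± 18.6. Hbb, a haemoglobin subunit whose reads may be shared with close paralogs, was at 237 ± 228 and 121 ± 99.5 CPM and was lower in SPS in all 3 pairs. Its log2 fold change of −0.98 became 0.18 without Control replicate 2, −0.59 without SPS replicate 1 and −1.88 without SPS replicate 2. Adjusted over the list alone, Hbb among the 5 blood cell markers was the 1 gene that passed with the replicate block, and 0 members of any list passed without it.

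Some of the genes with the smallest p belonged to no list. The locus named Ncbp2, a nuclear cap-binding subunit (ENSRNOG00000001746, chromosome 11, 72071838 to 72080928), was at 0.69 ± 0.43 CPM in Control and 12.6 ± 12.3 in SPS, with 16 reads in all Control libraries. It shares its symbol with another row of the table and its reads may be split. The locus named Fam50a (ENSRNOG00000045790, chromosome 4, 104949596 to 104956714) was at 3.16 ± 1.23 and 0.12 ± 0.21 CPM, with 4 reads in SPS replicate 1 and 0 in the other SPS libraries. The RefSeq annotation of GRCr8 places a gene of that name on chromosome X, so the row may be a copy and its reads uncertain. Nos3, the endothelial nitric oxide synthase (ENSRNOG00000009348, chromosome 4, 7314368 to 7342410, on a span that another gene shares), was at 14.6 ± 9.90 and 4.33 ± 0.89 CPM, and every SPS library was below every Control library. Its log2 fold change was −1.75 ± 0.67 (SE, unadjusted p = 0.0319 and adjusted p = 1.00 in edgeR), and −1.04 without Control replicate 2, where Nos3 was at 25.9 CPM and endothelial markers were also highest, at 0.92 above the mean of the 6 libraries. Plekhh1 was at 44.2 ± 10.7 and 101 ± 45.1 CPM, and its log2 fold change went from 1.19 to 0.76 without SPS replicate 2. Cbln1 and Cbln4, secreted synapse organisers, and Klhdc8a were at 92.4, 101 and 32.8 CPM in Control replicate 2 and at most at 12.3, 6.16 and 3.45 in the other 5 libraries.

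Libraries numbered 1 and 3 resembled their number more than their group. The correlation of log CPM over genes was 0.974 between Control and SPS replicate 1 and 0.957 between Control and SPS replicate 3, while Control replicates 1 and 3 correlated at 0.828 and SPS replicates 1 and 3 at 0.880. Those numbered 2 did not do so clearly. Control and SPS replicate 2 correlated at 0.772, and Control replicate 2 correlated more with Control replicate 1, at 0.888. SPS replicate 2 correlated at 0.777 with Control replicate 1 and at 0.765 with SPS replicate 1. The libraries also differed in how long their abundant transcripts were. Genes with an effective length under 0.5 kb lay at −0.98 and −1.01 on the log2 scale in Control and SPS replicate 3 and at 0.89 and 0.83 in Control and SPS replicate 2, relative to the mean of the 6 libraries.

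**Figure D3:**
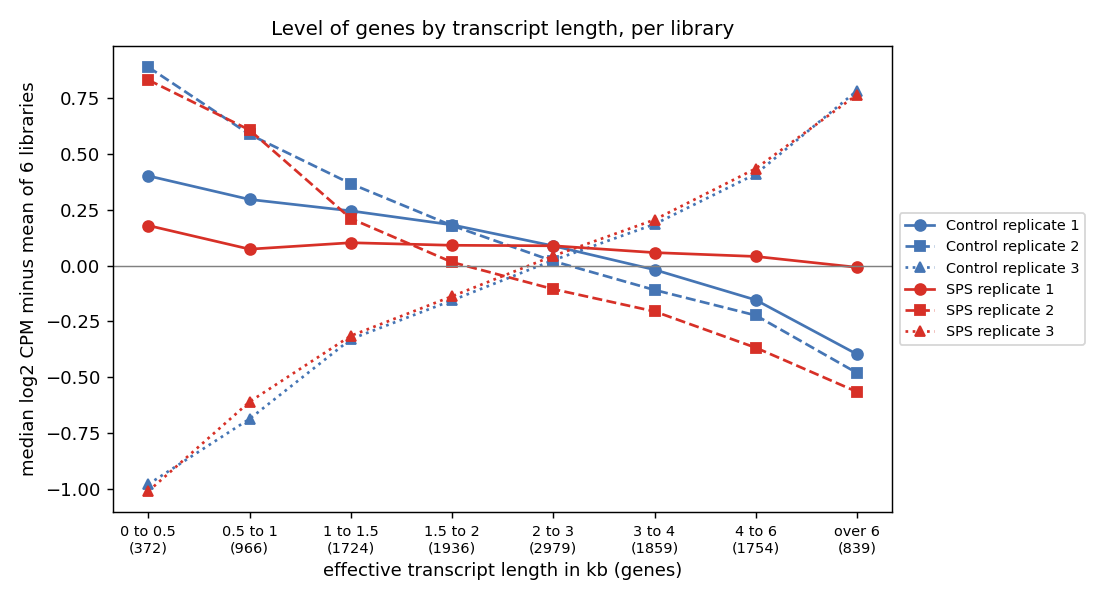
Median over genes of log2 CPM minus the gene's mean over the 6 libraries, by effective transcript length in kb, with the number of genes per bin in parentheses and 1 line per library (blue for Control, red for SPS, a line style and marker per replicate number). The libraries numbered 3 go from −0.98 and −1.01 in the shortest bin to 0.78 and 0.76 in the longest, and those numbered 2 go from 0.89 and 0.83 to −0.48 and −0.56.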

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

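Added after seeing the data, when the table was found to hold both units, was limma on log2(FPKM + 1) as an alternative, with and without the replicate block. Its other pseudocounts, scalings and robust variances were planned. Also added were the other count scalings, summed symbols, the counts as deposited, length correction, quality weights and leaving out both libraries numbered 2.

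Oligodendrocyte and ependymal markers passed camera at the preset correlation in all 25 alternative fits that gave list tests, with medians of 0.31 to 1.05 and 0.70 to 2.28. Of 60 named genes, 40 kept 1 direction in all alternatives. Of 200 alternative values of the 8 passing lists, 149 kept the call and 46 lost it with the same direction of the test, 17 of these for cortex and subiculum markers, 14 for mitochondrially encoded genes and 9 for monoamine and acetylcholine receptors. Pairing by replicate number, as a replicate block, left 0 genes by adjusted p, 49 at an unadjusted p under 0.05 and 2-fold, and 6 lists, and changed no other call than those of the 2 lists named above and of Hbb within the blood cell list. Depth limits genes with few reads most in SPS replicate 2, with 4081184 reads. Except where fewer samples or genes are the cause by construction, the cause of the changes below was not tested. Fits without 1 library had no replicate block, so the library of the same number stayed unmatched in the other group. Likeness by number can then enter the group difference. Ribosomal protein genes stood at 0.87 and 1.11 above the mean of the 6 libraries in Control and SPS replicate 2. Their median fold change was 0.41 without Control replicate 2 and −0.70 without SPS replicate 2, on the log2 scale.

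By adjusted p, 1 gene passed with library quality weights and the replicate block (LOC100360117) and 1 with both libraries numbered 2 left out and the replicate block (Gdf1), both named after their values were seen; all other settings gave 0. The count at an unadjusted p under 0.05 and 2-fold was 37 in the main analysis, 72 with DESeq2 (58 higher, 14 lower), 144 with no filter, 93 with quality weights, and 11 and 112 with both libraries numbered 2 left out, without and with the block. With limma on FPKM it was 61, 134 with the block, 58 and 62 at pseudocounts 0.1 and 0.01, 62 with median-ratio scaling (23 higher, 39 lower), 64 with quantile normalization (25 higher, 39 lower) and 57 with robust variances. Leaving out 1 library gave 11 to 217 genes and 6 to 15 lists. The passing lists, 8 in the main analysis, were 0 with an estimated correlation, 0 with fry, 6 with limma on log2(FPKM + 1), where median-ratio scaling gave 5 and quantile normalization 5, and 2 with both libraries numbered 2 left out (10 with the replicate block). Of the 32 lists that did not pass, 14 gained a call in at least 1 alternative, 31 calls in all. Leaving out 1 library gave 26 of them: 9 without Control replicate 2, 8 without SPS replicate 2, 6 without SPS replicate 3, 2 without Control replicate 3 and 1 without Control replicate 1. With both libraries numbered 2 left out and the replicate block, ribosomal protein genes (median −0.17, adjusted p = 0.000306), nuclear-encoded oxidative phosphorylation genes (−0.16, adjusted p = 0.000345), blood cell markers (−0.19, adjusted p = 0.0265) and GABA receptors and synthesis (0.11, adjusted p = 0.0428) passed camera. Some passed in the opposite direction when 1 library was left out: ribosomal protein genes without Control replicate 2 (0.41, adjusted p = 3.12e-05) and without SPS replicate 3 (0.33, adjusted p = 5.47e-06), and GABA receptors and synthesis without SPS replicate 3 (−0.44, adjusted p = 0.0306). Synaptic vesicle genes passed with length correction and block (−0.24, adjusted p = 0.0246).

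Direction reversed for some genes, given as log2 fold changes. With both libraries numbered 2 left out, without and with the replicate block, the values were −0.58 and −0.78 for Aif1, 0.18 and 0.21 for Calb1, 0.18 and 0.27 for Cbln4, −0.51 and −0.19 for Clic6, 0.0051 and 0.090 for Cux2, 0.38 and 0.12 for Fos, −0.17 and −0.17 for Gfap, −0.31 and −0.38 for Kcne2, 0.087 and 0.16 for Ntrk2, 0.022 and 0.024 for Tsc22d3, −1.12 and −0.58 for Ttr, and 0.13 and 0.17 for the median of monoamine and acetylcholine receptors, which passed camera in the opposite direction with the block (adjusted p = 0.0361) and not without it (adjusted p = 0.102). Klf4 was at 0.022 without the block, and with it Sgk1 at −0.014 and cortex and subiculum markers at 0.060. Quality weights gave −0.27 for Aif1, 0.44 for Fos, −0.037 for Gfap and 0.092 for Ntrk2. With limma on log2(FPKM + 1), with the block or robust variances, Aif1 was at −0.38 and Ntrk2 at 0.030; at pseudocounts 0.1 and 0.01 Aif1 was at −0.42 and −0.42 and Ntrk2 at 0.031 and 0.031. Median-ratio scaling gave −0.42 for Aif1, and quantile normalization −0.42 for Aif1 and 0.050 for Ntrk2. Ntrk2 was at 0.011 with no normalization factors. Aif1 was at −0.36 with the replicate block and −0.30 with length correction and block, where Cnr1 was at −0.0031.

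Leaving out 1 library, the ranges were −0.37 to 0.21 for Fkbp5, −0.38 to 1.53 for Nr3c2, −0.51 to 0.83 for Nr3c1, −0.69 to 0.93 for Cnr1, −1.50 to 0.12 for Cux2, −0.96 to 0.43 for Fos, −0.023 to 0.31 for Gfap, −1.88 to 0.18 for Hbb, −0.29 to 0.34 for Sgk1, −1.02 to 0.56 for Aif1, −0.67 to 0.60 for Ntrk2, −0.58 to 0.00091 for Bdnf, −0.15 to 7.07 for Clic6, −0.21 to 5.14 for Kcne2, −0.0035 to 1.11 for Olig2, −0.39 to 0.051 for Tsc22d3, −0.76 to 9.03 for Ttr, −0.21 to 4.74 for choroid plexus markers and −0.93 to 0.047 for monoamine and acetylcholine receptors.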

Other observations

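All tests in this part were chosen after the result was seen, except those of transcript length and sequencing depth and the splits of the samples.

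Markers of pericytes and fibroblasts, endothelium and blood were highest in the libraries numbered 2. Pericyte and fibroblast markers stood at 1.35 and 1.17 above the mean of the 6 libraries on the log2 scale in Control and SPS replicate 2, against −0.78, −0.65, −0.73 and −0.13 in Control replicates 1 and 3 and SPS replicates 1 and 3. Endothelial markers were at 0.92 and 0.59 in the pair numbered 2, and blood cell markers at 1.19 and 0.88. Among genes chosen after their values were seen, Ptgds, a prostaglandin D synthase of the meninges, was at 4719 CPM in Control replicate 2 and 2259 in SPS replicate 2, and at most at 222 in the others. Igf2, a growth factor of meninges and choroid plexus, was at 469 and 1111 CPM, against at most 151. Cytosolic ribosomal protein genes were at 0.87 and 1.11 in the pair numbered 2 and at −1.20 and −1.03 in the pair numbered 3.

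Choroid plexus markers were very high in SPS replicate 2, with Ttr at 31254 CPM, and Enpp2, 1 of the 13 tested markers, is also an oligodendrocyte marker. An effect of stress in all stressed samples would need a similar rise in SPS replicates 1 and 3. There the median difference in mean log2 CPM from the controls was −0.13, with an SD over the markers of 0.96. The 3.28 with all 3 libraries is an edgeR fold change, a different measure in which 1 very high library weighs more. The like edgeR median without SPS replicate 2 was −0.21. In log2 CPM the pair medians were 0.49, 5.55 and −0.22 for replicates 1, 2 and 3. Choroid plexus tissue, which borders the hippocampus, in that library and a response of that 1 sample to stress both stay open as hypotheses. Of the 11 markers with reads in too few libraries, or too few reads, to be tested, 9 had their highest share of reads there, with Slc4a5 at 2578 reads and Kl at 2039. Both hypotheses predict that count, and markers read in 1 library alone were left untested for that reason, so the hypotheses cannot be told apart here.

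The likeness of libraries with the same number was set against technical explanations. If recovery by transcript length were the whole of it, removing the length trend of each library would bring the lowest same-number correlation of deviations under 0.1, and it was 0.31 after the correction against 0.37 before, although the trend held 10.0% of the spread. With all libraries thinned to 4081184 reads the lowest correlation was 0.39. The lowest was that of number 2 each time, which centring on group means can hold up while numbers 1 and 3 stay alike. So it cannot speak separately against length or depth for number 2. Numbers 1 and 3 stood at 0.39 and 0.60 after the length correction, and at 0.41 and 0.69 after thinning. Those values argue against length or depth as the whole of their likeness. A shared day, litter or preparation per number could give the same likeness; the labels name none and it was not tested.

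Higher oligodendrocyte transcripts in SPS did not rest on SPS replicate 2 alone, since the median without it was 0.48 and the list passed camera at the preset correlation. With an estimated correlation the list did not pass even over all 6 libraries (adjusted p = 0.551). The fit without SPS replicate 2 kept Control replicate 2 unmatched, the library lowest in these markers (−0.66 relative to the mean of the 6 libraries). Without both libraries numbered 2 the median was 0.31. A lower share of neurons would raise other glial and endothelial markers alike, but oligodendrocyte markers exceeded those of astrocytes, microglia and endothelium by 0.94 (95% bootstrap interval over genes 0.80 to 1.09). That interval treats genes as independent and holds no spread between samples, so it overstates the precision. By pair, the oligodendrocyte medians were 0.28, 1.47 and 0.35, and those of the other types were at most 0.16. More fimbria and ventricle lining in the stressed samples could bring both cell types, and so could an effect of stress on both. The markers themselves do not separate the 2: 18 of 21 oligodendrocyte markers were higher in all 3 pairs, and the lowest of the 3 pair medians of ependymal markers, whose levels had been seen before, was 0.79 with an SE over genes of 0.41. Both stay open and cannot be told apart here, as these libraries hold no measure of the dissected tissue.

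The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes by adjusted p, and the highest of the others 0, so 10 of 10 splits gave as many. It gave 37 genes at an unadjusted p under 0.05 and at least 2-fold, against up to 2215 in the others, and 7 splits gave as many. It gave 8 gene lists, against up to 18, and 8 splits gave as many. Of the 4 splits that part all 3 pairs, the real one gave 37 genes and the others 29, 19 and 28, with 8 lists against 6, 6 and 10. The 6 splits that part 1 pair and keep the other two together gave 196 to 2215 genes, which points to a structure of the samples by number.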
